A study of Ovis aries with 12 samples.

How the data were processed

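Whole-transcriptome RNA-seq was done on 12 sheep embryo libraries, 3 for each of 4 groups made of breed (Hulunbuir or Ujumqin) and embryo age (16 or 25 days). Per the labels' protocols, total RNA was isolated with TRIzol reagent and Illumina libraries were made from it. Per the submitters' processing notes, reads were handled with cutadapt 1.9 and FastQC and the Oar_v3.1 sheep genome was used. The aligner, the counting program and the FPKM program are not given in the sources used here, nor is whether counting used strand or whether a count is a read or a read pair.

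The deposited table lists 26247 genes, each with a count and an FPKM value for the 12 libraries, per the file headers. The deposited count columns hold whole numbers that are not scaled between libraries. The deposited FPKM values (fragments per kilobase of gene, scaled by library size) equal the counts times a gene factor and 1 factor per library: over 8029 genes with more than 200 counts in each library, the ratio of count to FPKM ranged between libraries by a median of 0.0802% (95th percentile 0.307%) after that factor was removed. Where a count is 0 the FPKM is written as 0.0001. A symbol stood in the table for 14418 genes. Of the 15439 genes with an NCBI gene number, 15024 were found in a RefSeq gene table, which named 1300 more, used for names alone. A further 2625 entries carry only an RNA family name and 10529 only an identifier. No genome sequence was used here. Each of the 12 libraries was matched to its columns by name, 0 columns of samples were left over and 0 entries named no gene.

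Before the data were examined, limma on log2(FPKM + 1) was chosen, with edgeR in its place if counts were found. Counts were found, so edgeR 4.0.16 in R 4.3.3 gave the main results: genes with FPKM of at least 1 in at least 3 of the 12 libraries (14595) were kept, libraries were scaled by TMM, and a quasi-likelihood negative binomial fit with 4 group means over 12 libraries gave two-sided tests with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The contrasts were Hulunbuir minus Ujumqin at each age, day 25 minus day 16 in each breed, and the breed by age interaction. A standard error is the absolute log2 change divided by the square root of the F statistic. FPKM in the text are as deposited, whereas log2 changes come from the count fit. The floor of 3 counts in a library corresponds to 0.0541 to 0.0985 CPM, and floors cover counting error only.

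The same choices, made in advance, fixed 29 gene lists with 869 distinct symbols, of which 728 were in the table. They cover tissues (trophoblast and placenta, yolk sac with endoderm and liver, erythroid, epiblast, primitive streak and tail bud, neural, neural crest, somite and muscle, heart, sclerotome, limb bud, mesenchyme, endothelium, intermediate mesoderm, epidermis), patterning (posterior HOX, anterior and middle HOX), other cell types (leukocytes, uterine endometrium) and processes (interferon response, immediate early and tissue dissociation, cell cycle, glycolysis, Wnt, BMP and TGF-beta, fat tail candidates, ribosomal proteins, nuclear respiratory chain, mitochondrially encoded). Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the lists of a contrast, and again with an estimated correlation.

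Genes with a symbol were named by a rule fixed at the same time. It took, per contrast between 2 groups, called genes with a mean of at least 5 FPKM in the higher group and no overlap between the 3 and 3 libraries (chance gives 10%), the 8 largest rises and 8 largest falls in log2(FPKM + 1). It also took, per list, up to 2 called members per direction and contrast and up to 2 uncalled members with the highest mean FPKM, 11 tail and axis genes, the 6 interaction genes with the smallest adjusted p, and the 5 genes with the highest mean FPKM in each group. Not every gene the rule took is printed, and some results are not reported here.

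The fit was tested on simulated counts with 200 of the 14595 genes changed. With 1 spread for all libraries, 21% of 2-fold and 72% of 4-fold changes were recovered for breed at day 16, 19% and 60% for breed at day 25, 9% and 67% for age in Ujumqin, 9% and 68% for age in Hulunbuir and 1% and 28% for the interaction, with 6, 4, 1, 5 and 4 false calls. With the spread of each age simulated, 86 of 193 calls were false at day 16, 0 of 79 at day 25, 8 of 92 and 7 of 98 for the ages and 8 of 42 for the interaction. In the 6 libraries of an age alone, 1 of 15 calls was false at day 16 and 12 of 162 at day 25. Of 4-fold changes 13% and 90% were recovered. Camera called only the raised simulated list of 25 genes in each contrast. With day 16 breed labels mixed it called 8 to 17 real lists.

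Replicates were compared before averaging: Pearson r within a group lay between 0.894 and 0.992, and chi-square per degree of freedom between 16.5 and 610, so that each library was counted on its own. Between breeds, day 16 libraries labelled with the same replicate number deviated together from group means (r of 0.189, 0.302 and 0.356 across genes). Each r exceeded 0.1, so the numbers were taken as possible pairs, unused in the main fit. These come from the data, with few matchings to compare, as the labels name no shared animal or day.

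Alternatives chosen in advance were another pseudocount (0.1), no expression filter, FPKM rescaled to a common sum, median-of-ratios scaling, quantile normalization, a 2-fold criterion, the replicate number as a block, fits of the 6 libraries compared, and fits without each library. Alternatives added after the data were seen were limma on log2(FPKM + 1), DESeq2 1.42.0 and voom with a weight per group, more settings for the lists and the overlap, and log2(FPKM + 1) for the breed and age correlation. The pseudocount, rescaling and quantile settings were run with limma. A fold change on the log2(FPKM + 1) scale understates the change of low genes. Splice variants and sequence variants were not analysed here.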

Results

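RNA was sequenced in bulk from embryos of 2 breeds of Mongolian sheep (Ovis aries), after the embryos had been taken apart enzymatically into cell suspensions. Hulunbuir short-tail sheep were the experimental breed and Ujumqin sheep the control breed. Embryos of both breeds were sampled at day 16 and at day 25, with 3 libraries in each of the 4 groups. Total gene counts per library lay between 49944437 and 55455815 in Ujumqin and between 43131962 and 51241161 in Hulunbuir at day 16, and between 30464606 and 33171681 in Ujumqin and between 32625184 and 39643588 in Hulunbuir at day 25. Between 16794 and 17995 genes had a count in a library, and 14595 of the 26247 listed genes passed the expression filter and were tested. The labels do not say whether the 3 libraries of a group came from separate animals, so p-values measure the spread between these samples, which can be technical. Gene positions are those of the Oar_v3.1 assembly.

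AHSG, which encodes the fetal plasma protein fetuin-A, had the highest mean in Ujumqin day 16 embryos, at 20028 ± 11389 FPKM (mean ± SD, n = 3 here and below). The acute-phase protein gene ORM1 (8397 ± 5003) and SERPINA1 (6285 ± 5874) followed. In Hulunbuir day 16 embryos the mitochondrial gene CYTB led with 7466 ± 1412 FPKM, and AHSG reached 3802 ± 2909. CYTB also led in Ujumqin day 25 embryos (10539 ± 1788), ahead of ribosomal protein genes such as RPL31 (9294 ± 1032). In Hulunbuir day 25 embryos the embryonic zeta globin gene HBZ led with 15669 ± 1556 FPKM, followed by AHSG (10249 ± 478). The first principal component of log2(FPKM + 1) took 55.1% of the variance and separated the ages, and the next took 15.6%. Libraries of a group lay farther apart at day 16 than at day 25: the biological coefficient of variation was 43.8% over the 6 day 16 libraries and 18.1% over the 6 day 25 libraries.

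**Figure D1:**
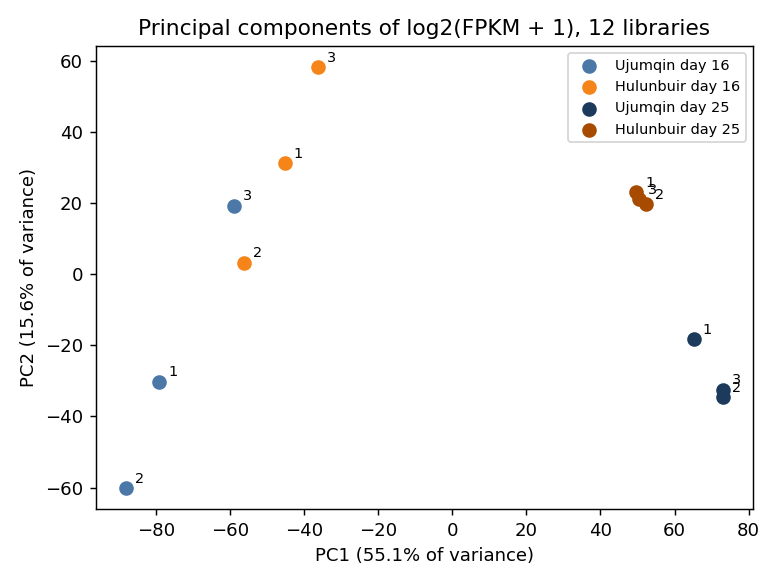
Principal components 1 and 2 of log2(FPKM + 1) over 14595 genes for the 12 libraries, with axes giving the share of variance and points numbered by replicate. Day 16 libraries have component 1 scores from -88.14 to -36.17 and day 25 libraries from 49.72 to 73.1, and the 3 Hulunbuir day 25 libraries lie closest together.

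At day 16, the comparison of the short-tailed with the control breed found blood, yolk sac and liver transcripts lower in Hulunbuir embryos and heart muscle transcripts higher. HBZ (chromosome 24, 133194 to 134250) was at 1618 ± 1444 FPKM in Ujumqin and 87.1 ± 31.1 in Hulunbuir (log2 change -4.22 ± 0.55, adjusted p = 0.00229). SERPINA1, the gene of the plasma protease inhibitor alpha-1-antitrypsin (chromosome 18, 57912144 to 57916083), was at 6285 ± 5874 FPKM in Ujumqin and 363 ± 282 in Hulunbuir (log2 change -4.07 ± 0.75, adjusted p = 0.0075). NKX2-5, a transcription factor of the early heart (chromosome 16, 4945135 to 4947613), was at 3.1 ± 1.44 FPKM in Ujumqin and 25.7 ± 10.4 in Hulunbuir (log2 change 2.94 ± 0.46, adjusted p = 0.00421). ACTC1, which encodes cardiac alpha-actin (chromosome 7, 27279050 to 27284876), was at 98.3 ± 49.4 FPKM in Ujumqin and 586 ± 215 in Hulunbuir (log2 change 2.48 ± 0.34, adjusted p = 0.00252). With the replicate number as a block in the 6 day 16 libraries, HBZ (0.0542) and SERPINA1 (0.0693) lost their calls. Without the block, each gene given by symbol with a day 16 breed call, except ITGA7, lost it in those libraries (0.0627 to 0.166). Adjusted p-values here and below are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and log2 changes are given with their standard errors.

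The erythroid genes moved as a group at day 16: 0 of 25 tested were higher in Hulunbuir, 17 lower and 8 not called. Erythroid counts adjusted over the list alone were 0 and 23, and camera gave adjusted p = 6.2e-21 (adjusted p = 0.336 with an estimated correlation). The red cell nuclear protein gene HEMGN and SLC4A1, which encodes the anion exchanger of the red cell membrane, fell with HBZ: HEMGN (-5.11 ± 0.60) and SLC4A1 (62.8 ± 54.9 and 3.28 ± 2.08 FPKM, log2 change -4.29 ± 0.67). Among yolk sac, endoderm and liver genes, 2 of 32 tested were higher in Hulunbuir, 16 lower and 14 not called. Yolk sac and liver counts adjusted over the list alone were 2 and 19, and camera gave adjusted p = 8.1e-11 (adjusted p = 0.336 with an estimated correlation). TTR, the gene of the thyroid hormone carrier transthyretin, was lower as well, at 532 ± 349 FPKM in Ujumqin and 38.3 ± 27.5 in Hulunbuir (log2 change -3.77 ± 0.59, adjusted p = 0.00421). The block in the 6 libraries took the calls of SLC4A1 (0.0559) and TTR (0.0555). The mean level of the erythroid list, in log2(FPKM + 1), was 4.02, 3.73 and 5.22 in the 3 Ujumqin libraries and 1.93, 2.58 and 2.71 in the 3 Hulunbuir libraries.

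Heart muscle genes stood higher in Hulunbuir day 16 embryos: 11 of 22 tested were higher in Hulunbuir, 0 lower and 11 not called. Heart counts adjusted over the list alone were 14 and 0, and camera gave adjusted p = 8.2e-11 (adjusted p = 0.336 with an estimated correlation). Other rises were in the myosin chaperone gene UNC45B (2.64 ± 0.33) and the heart and pharynx transcription factor gene NKX2-6, at 0.617 ± 0.404 FPKM in Ujumqin and 8.09 ± 4.31 in Hulunbuir (log2 change 3.56 ± 0.81, adjusted p = 0.0203). NKX2-6 lost its call without Ujumqin replicate 1 or 2 (highest adjusted p 0.0521). Somite and skeletal muscle genes went the same way: 7 of 26 tested were higher in Hulunbuir, 0 lower and 19 not called. Muscle counts adjusted over the list alone were 13 and 0, and camera gave adjusted p = 3.3e-07 (adjusted p = 0.348 with an estimated correlation). ITGA7, which encodes a laminin receptor subunit of muscle and lies on chromosome 3, 163469104 to 163492706, was at 1.15 ± 0.179 FPKM in Ujumqin and 8.29 ± 0.373 in Hulunbuir (log2 change 2.79 ± 0.19, adjusted p = 1.2e-04).

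At day 16, among genes of the primitive streak, presomitic mesoderm and tail bud, 7 of 27 tested were higher in Hulunbuir, 0 lower and 20 not called. Primitive streak counts adjusted over the list alone were 11 and 0, and camera gave adjusted p = 4.1e-05 (adjusted p = 0.336 with an estimated correlation). The protocadherin gene PCDH8 was at 0.45 ± 0.234 FPKM in Ujumqin and 1.44 ± 0.44 in Hulunbuir (log2 change 1.62 ± 0.38, adjusted p = 0.018), with 0.0553 without Hulunbuir replicate 1 and 0.0763 after quantile normalization. PCDH8 also lost its call with the block in the 6 libraries (0.133) and by voom with group weights (0.173). Among anterior and middle HOX genes, 10 of 20 tested were higher in Hulunbuir, 0 lower and 10 not called. Anterior HOX counts adjusted over the list alone were 12 and 0, and camera gave adjusted p = 4.7e-06 (adjusted p = 0.336 with an estimated correlation). HOXB1 (2.82 ± 1.62 and 16.3 ± 11.4 FPKM, log2 change 2.39 ± 0.60, adjusted p = 0.0223) was an example. Its call was lost without Ujumqin replicate 2, Hulunbuir replicate 1 or Hulunbuir replicate 3 (highest adjusted p 0.0679) and by voom (0.0921). For posterior HOX genes, which pattern the hind trunk and tail, 0 of 10 tested were higher in Hulunbuir, 0 lower and 10 not called. Posterior HOX counts adjusted over the list alone were 0 and 0, and camera gave adjusted p = 0.888. Of the endothelial genes, 3 of 17 tested were higher in Hulunbuir, 0 lower and 14 not called. Endothelial counts adjusted over the list alone were 9 and 0, and camera gave adjusted p = 3.0e-05 (adjusted p = 0.382 with an estimated correlation). The receptor tyrosine kinase genes TIE1 (15.8 ± 1.73 and 38.5 ± 3.55 FPKM, log2 change 1.23 ± 0.15) and FLT4 (1.84 ± 0.27) were among them. In the sclerotome and cartilage list, 7 of 19 tested were higher in Hulunbuir, 1 lower and 11 not called. Sclerotome counts adjusted over the list alone were 10 and 1, and camera gave adjusted p = 0.00501 (adjusted p = 0.382 with an estimated correlation). Cartilage collagen and a cartilage-secreted protein led it: COL2A1 (72.1 ± 34.9 and 315 ± 110.2 FPKM, log2 change 2.05 ± 0.34) and MIA (2.88 ± 0.40). Without Hulunbuir replicate 3 the sclerotome list lost its call (0.0652). TIE1 (0.0560) and MIA (0.0624) lost theirs with the block in the 6 libraries, and MIA by voom (0.221).

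Of the trophoblast and placenta list, 0 of 17 tested were higher in Hulunbuir, 7 lower and 10 not called. Trophoblast counts adjusted over the list alone were 0 and 7, and camera gave adjusted p = 0.00425 (adjusted p = 0.41 with an estimated correlation). PPARG, a nuclear receptor of trophoblast and fat cells, was at 35.3 ± 35.2 FPKM in Ujumqin and 1.36 ± 1.41 in Hulunbuir (log2 change -4.69 ± 0.92, adjusted p = 0.00903), with 0.0764 by voom. KRT8, an epithelial keratin gene, was not called at 2139 ± 815 FPKM in Ujumqin and 2906 ± 1479 in Hulunbuir (log2 change 0.40 ± 0.44, adjusted p = 0.549). The trophoblast list level was 4.96, 5.51 and 3.54 in the 3 Ujumqin day 16 libraries and 3.97, 3.93 and 3.25 in the Hulunbuir ones, and without Hulunbuir replicate 3 its adjusted p was 0.0663. For uterine endometrium markers, a tissue that can adhere to an embryo, 1 of 13 tested were higher in Hulunbuir, 4 lower and 8 not called. Endometrium counts adjusted over the list alone were 1 and 5, and camera gave adjusted p = 0.0212 (adjusted p = 0.336 with an estimated correlation). The set lost its call without Ujumqin replicate 1 (0.0570) or Hulunbuir replicate 3 (0.0717) and with the replicate block in the 6 libraries (0.0667). Among the largest falls, S100G, a vitamin D-dependent calcium-binding protein gene, was at 303 ± 201 FPKM in Ujumqin and 6.5 ± 6.04 in Hulunbuir (log2 change -5.53 ± 0.75, adjusted p = 0.00252).

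At day 16, in the immediate early and tissue dissociation list, whose genes sample handling can induce, 1 of 28 tested were higher in Hulunbuir, 9 lower and 18 not called. Immediate early counts adjusted over the list alone were 3 and 10, and camera gave adjusted p = 0.00425 (adjusted p = 0.472 with an estimated correlation). The transcription factor genes KLF4 (9.68 ± 1.29 and 0.6996 ± 0.23 FPKM, log2 change -3.84 ± 0.34) and FOSB (91.1 ± 77.1 and 3.71 ± 1.46 FPKM, log2 change -4.74 ± 1.09, adjusted p = 0.0172) fell. FOSB had 0.0502 without Hulunbuir replicate 3 and up to 0.0926 in the 4 limma fits, 0.209 with the block in the 6 libraries and 0.449 by voom, and the list had an adjusted p of 0.0820 without Ujumqin replicate 2. The stress-induced genes NUPR1 (78 ± 49.8 and 4.11 ± 2.42 FPKM, log2 change -4.28 ± 0.58) and DDIT4 (2.45 ± 0.39) moved in opposite directions. B2M, the light chain gene of major histocompatibility complex class I, was at 767 ± 885 FPKM in Ujumqin and 38.3 ± 8.97 in Hulunbuir (log2 change -4.46 ± 0.90, adjusted p = 0.00991), a call lost with the block in the 6 libraries (0.170) and by voom (0.148). For mesenchyme and extracellular matrix genes, 2 of 27 tested were higher in Hulunbuir, 1 lower and 24 not called. Matrix counts adjusted over the list alone were 2 and 1, and camera gave adjusted p = 0.778, with a positive median, a negative mean and a direction up in the test. COL3A1, a fibrillar collagen gene, was at 2928 ± 114 FPKM in Ujumqin and 2751 ± 2398 in Hulunbuir (log2 change -0.06 ± 0.52, adjusted p = 0.951). Without Hulunbuir replicate 2, whose COL3A1 share of counts was 3.50%, COL3A1 had an adjusted p of 0.00462 and the matrix list was called in the opposite direction at 0.00579.

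Of the 14595 genes tested at day 16, 1235 were higher and 1224 lower in Hulunbuir, and 681 and 813 of these changed at least 2-fold. On FPKM rescaled to a common sum per library, 65.1% of called genes were higher instead of 50.2%, and the median log2 change was 0.13. The count of 2459 came from a spread shared with the more uniform day 25 libraries. The 6 day 16 libraries fitted alone gave 3 genes, with 2955 at an unadjusted p under 0.05, and DESeq2 on the 12 libraries gave 3696. The replicate number as a block in the 6 libraries gave 293, and voom with a weight per group 487. The 3 genes were ITGA7, ENSOARG00000002632 on chromosome 16, 4692 to 25575 (0.164 and 10.9 FPKM) and ENSOARG00000015872 on chromosome 3, 57376943 to 57377383 (75.9 and 10.3 FPKM), each with an adjusted p of 0.0261 and each named after its values were seen. Without Ujumqin replicate 2 the count was 1167 and without Hulunbuir replicate 1 it was 1527. Of 30 genes called at day 16 and checked in each setting, 1 was still called with the 6 libraries and 18 with the block added.

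At day 25, blood and liver transcripts were higher in Hulunbuir embryos, and ribosomal protein, matrix and immediate early or dissociation transcripts were lower. The erythroid transcription factor gene KLF1 (chromosome 5, 10751045 to 10754475) was at 3.41 ± 0.899 FPKM in Ujumqin and 47.4 ± 1.92 in Hulunbuir (log2 change 3.41 ± 0.65, adjusted p = 0.00729). ALAS2, whose enzyme starts heme synthesis in red cells (chromosome X, 47828609 to 47849887), was at 39.9 ± 2.9 FPKM in Ujumqin and 368 ± 4.98 in Hulunbuir (log2 change 2.83 ± 0.47, adjusted p = 0.00433). SERPINF2, the liver gene of alpha-2-antiplasmin (chromosome 11, 22453045 to 22458842), was at 5.01 ± 1.88 FPKM in Ujumqin and 55.5 ± 2.63 in Hulunbuir (log2 change 3.11 ± 0.45, adjusted p = 0.00259). RPL22, a protein of the large ribosomal subunit (chromosome 12, 45246240 to 45251689), was at 3365 ± 457 FPKM in Ujumqin and 1701 ± 86.4 in Hulunbuir (log2 change -1.36 ± 0.16, adjusted p = 0.00121). COL1A1, the main bone and skin collagen gene, was at 2855 ± 1208 FPKM in Ujumqin and 919.8 ± 15.7 in Hulunbuir (log2 change -1.99 ± 0.47, adjusted p = 0.0173). Its call was lost without Ujumqin replicate 1 or any of the 3 Hulunbuir replicates (highest adjusted p 0.0685). FPKM are as deposited, and on that scale the median gene lay 0.29 log2 units higher in Hulunbuir at day 25, whereas log2 changes are on TMM-scaled counts.

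Erythroid genes were called in nearly the whole list at day 25: 20 of 25 tested were higher in Hulunbuir, 0 lower and 5 not called. Erythroid counts adjusted over the list alone were 24 and 0, and camera gave adjusted p = 4.6e-19 (adjusted p = 0.534 with an estimated correlation). Red cell maturation genes led the list: HEMGN (12.3 ± 2.12 and 119.9 ± 6.65 FPKM, log2 change 2.93 ± 0.53) and the ubiquitin ligase gene TRIM58 (3.53 ± 0.71). The membrane protein gene GYPC was at 49.95 ± 7.06 FPKM in Ujumqin and 65.2 ± 3.17 in Hulunbuir (log2 change 0.01 ± 0.21, adjusted p = 0.983). In the yolk sac, endoderm and liver list, 11 of 32 tested were higher in Hulunbuir, 1 lower and 20 not called. Yolk sac and liver counts adjusted over the list alone were 14 and 1, and camera gave adjusted p = 3.0e-06 (adjusted p = 0.761 with an estimated correlation). The plasma protein gene VTN (4.37 ± 1.27 and 39.4 ± 0.748 FPKM, log2 change 2.81 ± 0.59, adjusted p = 0.0107) rose, with 0.0533 without Ujumqin replicate 3. The endoderm factor gene GATA6 (16 ± 6.89 and 8.11 ± 1.01 FPKM, log2 change -1.33 ± 0.29, adjusted p = 0.0121) fell, with 0.0594 without Hulunbuir replicate 1 and 0.0697 on FPKM rescaled to a common sum. AHSG was not called, at 2708 ± 756 FPKM in Ujumqin and 10249 ± 478 in Hulunbuir (log2 change 1.56 ± 0.54, adjusted p = 0.0701), but passed the threshold in 8 other settings (1.1e-04 to 0.0170).

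Among ribosomal protein genes at day 25, 0 of 56 tested were higher in Hulunbuir, 48 lower and 8 not called. Ribosomal counts adjusted over the list alone were 0 and 52, and camera gave adjusted p = 3.3e-31 (adjusted p = 0.534 with an estimated correlation). RPL27 (518 ± 76.7 and 121 ± 14.2 FPKM, log2 change -2.47 ± 0.43, adjusted p = 0.00512) had the largest fall. RPLP0, which encodes the ribosomal stalk base, was at 4107 ± 533 FPKM in Ujumqin and 4429.7 ± 181 in Hulunbuir (log2 change -0.27 ± 0.19, adjusted p = 0.354). The list's median log2 change was -0.86 with TMM scaling, -0.48 on FPKM as deposited, -0.37 on FPKM rescaled to a common sum and -0.14 with quantile normalization. At day 16, 0 of 56 tested were higher in Hulunbuir, 0 lower and 56 not called. Ribosomal counts adjusted over the list alone were 0 and 0, and camera gave adjusted p = 0.305, and the sign of that median depended on the scaling, from -0.07 with TMM to 0.09 with quantile normalization. For mitochondrially encoded genes at day 25, 0 of 13 tested were higher in Hulunbuir, 10 lower and 3 not called. Mitochondrial counts adjusted over the list alone were 0 and 11, and camera gave adjusted p = 1.4e-07 (adjusted p = 0.534 with an estimated correlation). Their median log2 change was -1.26 with TMM, -0.75 on FPKM rescaled to a common sum and -0.42 with quantile normalization. The respiratory complex subunit gene ND2 was at 1609.8 ± 443 FPKM in Ujumqin and 793 ± 10.03 in Hulunbuir (log2 change -1.40 ± 0.27, adjusted p = 0.0082). COX1 was not called at 8064 ± 1116 FPKM in Ujumqin and 4021 ± 269 in Hulunbuir (log2 change -1.38 ± 0.48, adjusted p = 0.0735), but was in 4 other settings (1.5e-04 to 0.0128).

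Matrix genes were lower in Hulunbuir at day 25: 1 of 27 tested were higher in Hulunbuir, 12 lower and 14 not called. Matrix counts adjusted over the list alone were 1 and 15, and camera gave adjusted p = 1.4e-07 (adjusted p = 0.534 with an estimated correlation). DCN, the gene of the small proteoglycan decorin, was at 892 ± 235 FPKM in Ujumqin and 287 ± 9.17 in Hulunbuir (log2 change -1.99 ± 0.44, adjusted p = 0.0125), a call lost without any of the 3 Hulunbuir replicates (highest adjusted p 0.0541). In the sclerotome and cartilage list, 0 of 19 tested were higher in Hulunbuir, 6 lower and 13 not called. Sclerotome counts adjusted over the list alone were 1 and 6, and camera gave adjusted p = 0.00454 (adjusted p = 0.534 with an estimated correlation). MIA, higher at day 16, was lower here at 137 ± 33.2 FPKM in Ujumqin and 47.2 ± 4.31 in Hulunbuir (log2 change -1.92 ± 0.36, adjusted p = 0.00698). In the immediate early and tissue dissociation list, 1 of 28 tested were higher in Hulunbuir, 10 lower and 17 not called. Immediate early counts adjusted over the list alone were 1 and 11, and camera gave adjusted p = 1.4e-06 (adjusted p = 0.534 with an estimated correlation). FOSB was at 27.9 ± 19.5 FPKM in Ujumqin and 1.17 ± 0.171 in Hulunbuir (log2 change -4.89 ± 1.13, adjusted p = 0.0149), with up to 0.0664 without any of the 3 Hulunbuir replicates. ATF3 (32.7 ± 7.42 and 5.31 ± 0.253 FPKM, log2 change -2.98 ± 0.62) and IER3 (-2.83 ± 0.33) fell too. MYC, of the same list, rose (19 ± 4.23 and 48.2 ± 2.34 FPKM, log2 change 0.98 ± 0.18). The neutrophil-attracting chemokine gene CXCL8 was at 7.38 ± 3.21 FPKM in Ujumqin and had 0 counts in Hulunbuir, at least 38.4-fold lower against a floor of 3 counts per library.

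Of the heart muscle genes, 5 of 22 tested were higher in Hulunbuir, 0 lower and 17 not called. Heart counts adjusted over the list alone were 5 and 0, and camera gave adjusted p = 0.0154 (adjusted p = 0.88 with an estimated correlation). NPPA, the atrial natriuretic peptide gene, was at 1.47 ± 0.288 FPKM in Ujumqin and 14.4 ± 2.93 in Hulunbuir (log2 change 2.91 ± 0.64, adjusted p = 0.0122). The heart list had an adjusted p of 0.0980 without Ujumqin replicate 1 and NPPA 0.0588 without Ujumqin replicate 3. For neural progenitors and neurons, 4 of 30 tested were higher in Hulunbuir, 1 lower and 25 not called. Neural counts adjusted over the list alone were 4 and 1, and camera gave adjusted p = 0.0255 (adjusted p = 0.88 with an estimated correlation), with 0.0666 without Ujumqin replicate 3. Among fat tail and adipose candidate genes, 1 of 11 tested were higher in Hulunbuir, 1 lower and 9 not called. Fat tail counts adjusted over the list alone were 2 and 1, and camera gave adjusted p = 0.594. HOXB9, a trunk-patterning gene, was the called posterior HOX gene at 14 ± 3.68 FPKM in Ujumqin and 37.6 ± 0.759 in Hulunbuir (log2 change 1.07 ± 0.27, adjusted p = 0.0209), with up to 0.0784 without any of the 5 day 25 libraries other than Ujumqin replicate 1. For trophoblast and placenta genes, 0 of 17 tested were higher in Hulunbuir, 1 lower and 16 not called. Trophoblast counts adjusted over the list alone were 0 and 0, and camera gave adjusted p = 0.365.

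**Figure D2:**
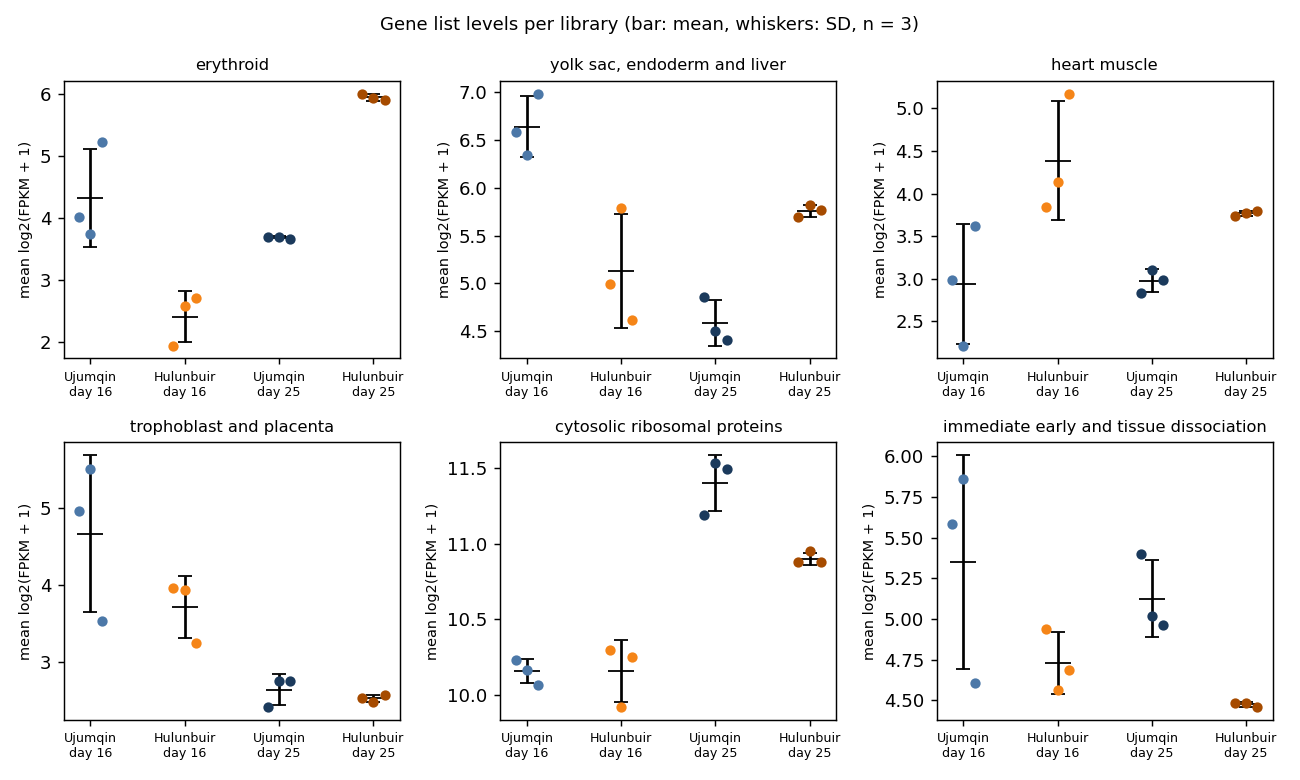
Mean log2(FPKM + 1) of 6 gene lists in each of the 12 libraries, with points for libraries, bars for the mean and whiskers for the SD of 3 libraries per group. The erythroid level in Hulunbuir was 2.41 ± 0.41 at day 16 and 5.95 ± 0.05 at day 25, against 4.32 ± 0.79 and 3.69 ± 0.02 in Ujumqin, and the ribosomal protein level of 11.40 ± 0.18 in Ujumqin at day 25 against 10.90 ± 0.04 in Hulunbuir depends on the scaling, as its median log2 change moves from -0.86 with TMM to -0.14 with quantile normalization.

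At day 25, 1150 genes were higher and 1290 lower in Hulunbuir, 599 and 440 of them by at least 2-fold. The split varied between settings: 47.1% of called genes were higher in the TMM fit, 44.7% with median-of-ratios scaling and 52.2% with quantile normalization, against 85.6% with limma on log2(FPKM + 1), 88.0% with a pseudocount of 0.1, 91.4% on FPKM rescaled to a common sum and 58.9% without the filter. In the last 4 the median log2 change was 0.29, 0.36, 0.39 and 0.06. The 6 day 25 libraries alone called 6716. The count fell to 898 or 927 without Ujumqin day 25 replicate 2 or 3. It fell to 923, 1009 or 1039 without Hulunbuir day 25 replicate 1, 2 or 3. Dropping 1 day 16 library gave 2208 to 2965.

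Between day 16 and day 25, neural, muscle, cartilage and interferon response transcripts rose in both breeds, and glycolysis, trophoblast and epithelial transcripts fell. MYH3, the embryonic skeletal myosin heavy chain gene (chromosome 11, 29149877 to 29169247), was at 0.0814 ± 0.0705 FPKM at day 16 and 45.4 ± 6.25 at day 25 (log2 change 9.24 ± 0.79, adjusted p = 5.4e-06) in Ujumqin. In Hulunbuir it was at 0.259 ± 0.113 FPKM at day 16 and 38.1 ± 1.35 at day 25 (log2 change 7.07 ± 0.71, adjusted p = 5.7e-05). LIN28A, an RNA-binding protein of early embryonic cells (chromosome 2, 239577200 to 239590412), fell in both, from 138 ± 59.6 to 0.946 ± 0.334 FPKM in Ujumqin (log2 change -7.00 ± 0.50, adjusted p = 2.3e-06) and from 348 ± 168 to 3.25 ± 0.368 in Hulunbuir (log2 change -6.85 ± 0.48, adjusted p = 6.3e-06). ISG15, an interferon-induced ubiquitin-like protein gene (chromosome 12, 49537787 to 49538733), was at 2.13 ± 1.35 FPKM at day 16 and 160.3 ± 9.66 at day 25 (log2 change 6.36 ± 0.47, adjusted p = 2.8e-06) in Ujumqin and rose by 8.78 ± 0.55 in Hulunbuir (adjusted p = 4.2e-06).

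Neural progenitor and neuron genes rose with age: 25 of 30 tested were higher and 0 lower at day 25 in Ujumqin, and 20 and 0 in Hulunbuir. Neural counts adjusted over the list alone were 27 and 0, and 22 and 0 in Hulunbuir. Neural genes had a camera adjusted p = 1.7e-10 (adjusted p = 0.361 with an estimated correlation) in Ujumqin and adjusted p = 4.0e-17 (adjusted p = 0.115 with an estimated correlation) in Hulunbuir. STMN4, a tubulin-binding protein gene of neurons, went from 0.0965 ± 0.0521 to 21.3 ± 2.83 FPKM in Ujumqin (log2 change 7.74 ± 0.65) and from 0.0407 ± 0.0704 to 23.4 ± 1.96 in Hulunbuir (8.72 ± 0.71). For somite and skeletal muscle genes, 19 of 26 tested were higher and 2 lower at day 25 in Ujumqin, and 13 and 3 in Hulunbuir. Muscle counts adjusted over the list alone were 19 and 2, and 15 and 3 in Hulunbuir. Muscle genes had a camera adjusted p = 4.0e-07 (adjusted p = 0.4004 with an estimated correlation) in Ujumqin and adjusted p = 7.9e-06 (adjusted p = 0.291 with an estimated correlation) in Hulunbuir. Sclerotome and cartilage genes rose too: 13 of 19 tested were higher and 2 lower at day 25 in Ujumqin, and 9 and 3 in Hulunbuir. Sclerotome counts adjusted over the list alone were 14 and 2, and 11 and 3 in Hulunbuir. Sclerotome genes had a camera adjusted p = 2.2e-06 (adjusted p = 0.198 with an estimated correlation) in Ujumqin and adjusted p = 0.00123 (adjusted p = 0.26 with an estimated correlation) in Hulunbuir. TWIST1, a mesenchyme transcription factor gene, rose in Ujumqin from 14 ± 5.99 to 174 ± 28.9 FPKM (3.78 ± 0.39). For its neural crest list, 7 of 17 tested were higher and 4 lower at day 25 in Ujumqin, and 7 and 2 in Hulunbuir. Neural crest counts adjusted over the list alone were 7 and 4, and 7 and 2 in Hulunbuir. Neural crest genes had a camera adjusted p = 0.436 in Ujumqin and adjusted p = 0.0847 in Hulunbuir, with 0.0199 in Hulunbuir without day 16 replicate 3, 0.0204 without the filter and 0.0222 with the block in the 6 libraries.

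Interferon response genes rose in both breeds: 15 of 23 tested were higher and 3 lower at day 25 in Ujumqin, and 16 and 0 in Hulunbuir. Interferon counts adjusted over the list alone were 16 and 4, and 17 and 0 in Hulunbuir. Interferon genes had a camera adjusted p = 6.2e-05 (adjusted p = 0.14 with an estimated correlation) in Ujumqin and adjusted p = 3.9e-12 (adjusted p = 0.005996 with an estimated correlation) in Hulunbuir. IFI6, a mitochondrial interferon-induced protein gene, went from 1.28 ± 1.13 to 326 ± 59.1 FPKM in Ujumqin (log2 change 8.10 ± 0.80) and from 0.376 ± 0.208 to 182 ± 15.6 in Hulunbuir (8.68 ± 0.86). For leukocyte markers, 5 of 15 tested were higher and 3 lower at day 25 in Ujumqin, and 7 and 0 in Hulunbuir. Leukocyte counts adjusted over the list alone were 5 and 2, and 8 and 1 in Hulunbuir. Leukocyte genes had a camera adjusted p = 0.0812 in Ujumqin and adjusted p = 1.4e-04 (adjusted p = 0.195 with an estimated correlation) in Hulunbuir. The Ujumqin leukocyte list had an adjusted p of 0.0236 without day 16 replicate 3. For anterior and middle HOX genes, 13 of 20 tested were higher and 0 lower at day 25 in Ujumqin, and 8 and 2 in Hulunbuir. Anterior HOX counts adjusted over the list alone were 13 and 0, and 8 and 2 in Hulunbuir. Anterior HOX genes had a camera adjusted p = 7.1e-04 (adjusted p = 0.361 with an estimated correlation) in Ujumqin and adjusted p = 0.0557 in Hulunbuir. The Hulunbuir list was called in 6 other settings, among them the replicate block (0.0381) and fits without Hulunbuir day 16 replicate 1 (0.0270) or 3 (0.0465) or day 25 replicate 3 (0.0493). For posterior HOX genes, 6 of 10 tested were higher and 0 lower at day 25 in Ujumqin, and 2 and 0 in Hulunbuir. Posterior HOX counts adjusted over the list alone were 4 and 0, and 2 and 0 in Hulunbuir. Posterior HOX genes had a camera adjusted p = 0.214 in Ujumqin and adjusted p = 0.049 (adjusted p = 0.61 with an estimated correlation) in Hulunbuir. The posterior call in Hulunbuir was lost with median-of-ratios scaling (0.0511), the replicate block (0.0521), the 6 libraries alone (0.0637) and without Hulunbuir day 16 replicate 3 (0.168).

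Blood and liver genes took different courses with age in the breeds. For erythroid genes, 3 of 25 tested were higher and 12 lower at day 25 in Ujumqin, and 23 and 0 in Hulunbuir. Erythroid counts adjusted over the list alone were 3 and 11, and 24 and 0 in Hulunbuir. Erythroid genes had a camera adjusted p = 0.274 in Ujumqin and adjusted p = 1.7e-21 (adjusted p = 0.171 with an estimated correlation) in Hulunbuir. HBZ went from 87.1 ± 31.1 to 15669 ± 1556 FPKM in Hulunbuir (log2 change 7.30 ± 0.64), together with the alpha globin chaperone gene AHSP (5.92 ± 0.66) and HEMGN (6.34 ± 0.63). In Ujumqin, HBM (2.31 ± 0.54) and GYPC (1.71 ± 0.22) rose, whereas the transferrin receptor gene TFRC fell from 33.7 ± 9.1 to 4.39 ± 0.7998 FPKM (-2.79 ± 0.19) as did the membrane skeleton gene ANK1 (-2.54 ± 0.55). HBM lost its call by voom with group weights (0.0628). For yolk sac, endoderm and liver genes, 1 of 32 tested were higher and 25 lower at day 25 in Ujumqin, and 8 and 8 in Hulunbuir. Yolk sac and liver counts adjusted over the list alone were 1 and 25, and 8 and 10 in Hulunbuir. Yolk sac and liver genes had a camera adjusted p = 6.3e-06 (adjusted p = 0.548 with an estimated correlation) in Ujumqin and adjusted p = 0.756 in Hulunbuir. In Hulunbuir that list had a negative median and a positive mean, and it was called at 0.0333 without day 16 replicate 2. HNF4A, a transcription factor gene of liver and yolk sac, was at 27 ± 8.78 FPKM at day 16 and 0.39 ± 0.0534 at day 25 (log2 change -5.95 ± 0.52, adjusted p = 6.2e-06) in Ujumqin. AMBP, a plasma protein precursor gene, rose in both, by 2.31 ± 0.65 in Ujumqin and 7.91 ± 0.85 in Hulunbuir. Hulunbuir rises included the fatty acid binding protein gene FABP1 (3.05 ± 1.59 and 378 ± 16.3 FPKM, log2 change 6.73 ± 0.50) and VTN (6.39 ± 0.72).

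Epithelial and trophoblast genes fell with age in both breeds. For trophoblast and placenta genes, 0 of 17 tested were higher and 13 lower at day 25 in Ujumqin, and 0 and 8 in Hulunbuir. Trophoblast counts adjusted over the list alone were 0 and 13, and 1 and 8 in Hulunbuir. Trophoblast genes had a camera adjusted p = 0.0142 (adjusted p = 0.619 with an estimated correlation) in Ujumqin and adjusted p = 0.0257 (adjusted p = 0.585 with an estimated correlation) in Hulunbuir. For epidermis and surface ectoderm genes, 0 of 14 tested were higher and 10 lower at day 25 in Ujumqin, and 0 and 10 in Hulunbuir. Epidermis counts adjusted over the list alone were 0 and 10, and 0 and 10 in Hulunbuir. Epidermis genes had a camera adjusted p = 0.00781 (adjusted p = 0.619 with an estimated correlation) in Ujumqin and adjusted p = 4.0e-05 (adjusted p = 0.375 with an estimated correlation) in Hulunbuir. For epiblast and pluripotency genes, 5 of 12 tested were higher and 7 lower at day 25 in Ujumqin, and 1 and 7 in Hulunbuir. Epiblast counts adjusted over the list alone were 5 and 7, and 1 and 7 in Hulunbuir. Epiblast genes had a camera adjusted p = 0.144 in Ujumqin and adjusted p = 0.0131 (adjusted p = 0.377 with an estimated correlation) in Hulunbuir, with 0.0571 without Hulunbuir day 16 replicate 3. NR6A1, a nuclear receptor gene of early embryos, fell in both (-6.32 ± 0.36 and -5.30 ± 0.33).

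Glycolysis and hypoxia genes fell: 2 of 29 tested were higher and 22 lower at day 25 in Ujumqin, and 0 and 23 in Hulunbuir. Glycolysis counts adjusted over the list alone were 2 and 24, and 0 and 23 in Hulunbuir. Glycolysis genes had a camera adjusted p = 0.00103 (adjusted p = 0.619 with an estimated correlation) in Ujumqin and adjusted p = 2.1e-12 (adjusted p = 0.195 with an estimated correlation) in Hulunbuir. The lactate transporter gene SLC16A3 (93.5 ± 25.9 and 6.67 ± 0.94 FPKM, log2 change -3.99 ± 0.48) and the glucose transporter gene SLC2A3 (-3.57 ± 0.28) led in Hulunbuir, and the hypoxia-induced gene NDRG1 (-3.22 ± 0.36) in Ujumqin. Of 56 ribosomal protein genes tested, 56 were higher and 0 lower at day 25 in Ujumqin, and 35 and 0 in Hulunbuir. Adjusted over the list alone, counts were 56 and 0, and 37 and 0. Camera gave adjusted p = 7.2e-18 in Ujumqin and 1.4e-07 in Hulunbuir (0.465 and 0.575 with an estimated correlation). For age, neither gene length nor list medians in other scalings were checked. For nuclear respiratory chain genes, 15 of 29 tested were higher and 5 lower at day 25 in Ujumqin, and 13 and 1 in Hulunbuir. Respiratory counts adjusted over the list alone were 15 and 5, and 14 and 1 in Hulunbuir. Respiratory genes had a camera adjusted p = 0.0691 in Ujumqin and adjusted p = 0.00161 (adjusted p = 0.61 with an estimated correlation) in Hulunbuir. The Ujumqin respiratory list was called without the filter (0.0448), without day 16 replicate 2 (0.00710) and without day 25 replicate 1 (0.0330). For mitochondrially encoded genes, 8 of 13 tested were higher and 1 lower at day 25 in Ujumqin, and 0 and 4 in Hulunbuir. Mitochondrial counts adjusted over the list alone were 8 and 1, and 0 and 4 in Hulunbuir. Mitochondrial genes had a camera adjusted p = 0.0591 in Ujumqin and adjusted p = 0.0389 (adjusted p = 0.675 with an estimated correlation) in Hulunbuir. ND5 fell in Hulunbuir (-2.06 ± 0.25), whereas in Ujumqin COX3 rose (2.01 ± 0.33). The Ujumqin mitochondrial list was called in 6 other settings, among them fits without the filter (0.0137), of the 6 libraries alone (0.0374) and without day 16 replicate 1 (0.0230) or 2 (0.0451) or day 25 replicate 1 (0.0113). The Hulunbuir mitochondrial call was lost with the replicate block (0.0630) and without day 16 replicate 2 (0.251) or day 25 replicate 2 (0.0597). For BMP and TGF-beta genes, 7 of 38 tested were higher and 17 lower at day 25 in Ujumqin, and 0 and 15 in Hulunbuir. BMP counts adjusted over the list alone were 7 and 17, and 0 and 16 in Hulunbuir. BMP genes had a camera adjusted p = 0.127 in Ujumqin and adjusted p = 1.2e-04 (adjusted p = 0.104 with an estimated correlation) in Hulunbuir, and the Ujumqin list was called without the filter (0.0448). For fat tail and adipose candidates, 1 of 11 tested were higher and 8 lower at day 25 in Ujumqin, and 0 and 6 in Hulunbuir. Fat tail counts adjusted over the list alone were 1 and 8, and 0 and 6 in Hulunbuir. Fat tail genes had a camera adjusted p = 3.6e-04 (adjusted p = 0.0971 with an estimated correlation) in Ujumqin and adjusted p = 6.1e-05 (adjusted p = 0.0295 with an estimated correlation) in Hulunbuir.

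For endothelial genes, 2 of 17 tested were higher and 8 lower at day 25 in Ujumqin, and 0 and 12 in Hulunbuir. Endothelial counts adjusted over the list alone were 2 and 8, and 0 and 12 in Hulunbuir. Endothelial genes had a camera adjusted p = 0.144 in Ujumqin and adjusted p = 1.1e-07 (adjusted p = 0.244 with an estimated correlation) in Hulunbuir, and the Ujumqin list was called without day 16 replicate 2 (0.0191). KDR, a vascular growth factor receptor gene, fell in both breeds (-3.44 ± 0.24 and -3.48 ± 0.24). For heart muscle genes, 7 of 22 tested were higher and 5 lower at day 25 in Ujumqin, and 2 and 12 in Hulunbuir. Heart counts adjusted over the list alone were 7 and 5, and 2 and 12 in Hulunbuir. Heart genes had a camera adjusted p = 0.826 in Ujumqin and adjusted p = 0.0039 (adjusted p = 0.61 with an estimated correlation) in Hulunbuir. NKX2-5 fell there from 25.7 ± 10.4 to 2.39 ± 0.908 FPKM (-3.53 ± 0.48). The Hulunbuir heart call was lost without day 16 replicate 3 (0.0672). For limb bud genes in Ujumqin, 9 of 18 tested were higher at day 25, 3 lower and 6 not called. Limb counts adjusted over the list alone were 9 and 3, and camera gave adjusted p = 0.0827. The list was called without the filter (0.0448) and without day 25 replicate 2 (0.0474). For intermediate mesoderm and mesonephros genes in Ujumqin, 3 of 17 tested were higher at day 25, 4 lower and 10 not called. Mesonephros counts adjusted over the list alone were 2 and 3, and camera gave adjusted p = 0.826. For Wnt signalling genes in Ujumqin, 16 of 51 tested were higher at day 25, 16 lower and 19 not called. Wnt counts adjusted over the list alone were 16 and 16, and camera gave adjusted p = 0.826. For cell cycle genes in Ujumqin, 9 of 35 tested were higher at day 25, 8 lower and 18 not called. Cell cycle counts adjusted over the list alone were 9 and 6, and camera gave adjusted p = 0.835, with negative median and mean and a direction up in the test.

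In Ujumqin 4481 genes were higher and 4803 lower at day 25, and in Hulunbuir 2758 and 3155. Of these, 2074 were higher and 2554 lower in both breeds, where 846.8 and 1038.3 would overlap if the lists were independent, and 178 genes went in opposite directions. The age contrasts correlated across genes with Pearson r = 0.65 and Spearman rho = 0.69, and genes are not independent replicates. On FPKM rescaled to a common sum, 31.4% of called genes were higher in Ujumqin instead of 48.3% (median log2 change -0.45) and 38.9% in Hulunbuir instead of 46.6% (-0.17). Limma on log2(FPKM + 1) gave 64.1% in Hulunbuir (0.12), or 63.98% with a pseudocount of 0.1 (0.15). In Ujumqin the median was -0.15 and -0.17 in those limma fits and -0.15 without the filter.

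The breed difference was then compared between the ages, as the breed by age interaction, in which a positive value means a breed difference more positive at day 25. BLVRB, whose enzyme acts in heme breakdown (chromosome 14, 48926673 to 48944336), was at 73.3 ± 26.7 and 13.4 ± 0.643 FPKM at day 16 in Ujumqin and Hulunbuir, and at 81.8 ± 9.65 and 369 ± 8.98 at day 25 (interaction 4.30 ± 0.31, adjusted p = 1.4e-04). The lysosomal protein gene CREG1 (chromosome 1, 117800762 to 117950033) was at 18.2 ± 4.78, 4.96 ± 0.795, 10.3 ± 0.985 and 39.8 ± 3.06 FPKM in the same order (3.53 ± 0.28, 1.4e-04). The organic cation transporter gene SLC22A4 (chromosome 5, 19640461 to 19682216) was at 2.31 ± 0.534, 0.348 ± 0.14, 0.975 ± 0.112 and 10.3 ± 0.806 (5.78 ± 0.46, 1.4e-04). FHL2, a muscle and stress-fibre LIM protein gene (chromosome 3, 97097485 to 97144958), was at 42.4 ± 5.21, 21 ± 2.23, 26.6 ± 2.39 and 108 ± 3.38 (2.72 ± 0.21, 1.4e-04). In the opposite direction, ITGA7 was at 1.15 ± 0.179, 8.29 ± 0.373, 3.21 ± 0.344 and 3.23 ± 0.368 (-3.15 ± 0.25, 1.4e-04). SLC22A17 (chromosome 7, 21187788 to 21195391) was at 7.69 ± 0.667, 21.7 ± 1.28, 61.4 ± 1.8 and 40.1 ± 1.99 (-2.41 ± 0.16, 8.5e-05).

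For erythroid genes, 23 of 25 tested had a positive interaction, 0 a negative one and 2 neither. Erythroid counts adjusted over the list alone were 25 and 0, and camera gave adjusted p = 1.8e-35 (adjusted p = 0.304 with an estimated correlation). For yolk sac, endoderm and liver genes, 19 of 32 tested had a positive interaction, 1 a negative one and 12 neither. Yolk sac and liver counts adjusted over the list alone were 24 and 2, and camera gave adjusted p = 6.1e-15 (adjusted p = 0.469 with an estimated correlation). Among ribosomal protein genes, 0 of 56 tested had a positive interaction, 32 a negative one and 24 neither. Ribosomal counts adjusted over the list alone were 0 and 43, and camera gave adjusted p = 4.7e-12 (adjusted p = 0.587 with an estimated correlation). Among mitochondrially encoded genes, 0 of 13 tested had a positive interaction, 9 a negative one and 4 neither. Mitochondrial counts adjusted over the list alone were 0 and 10, and camera gave adjusted p = 3.2e-07 (adjusted p = 0.57 with an estimated correlation). For heart muscle genes, 0 of 22 tested had a positive interaction, 3 a negative one and 19 neither. Heart counts adjusted over the list alone were 0 and 3, and camera gave adjusted p = 0.0147 (adjusted p = 0.694 with an estimated correlation), with 0.0851 without Ujumqin day 16 replicate 2 and 0.172 without Hulunbuir day 16 replicate 3. For somite and skeletal muscle genes, 0 of 26 tested had a positive interaction, 6 a negative one and 20 neither. Muscle counts adjusted over the list alone were 0 and 6, and camera gave adjusted p = 2.2e-04 (adjusted p = 0.587 with an estimated correlation). For sclerotome and cartilage genes, 1 of 19 tested had a positive interaction, 7 a negative one and 11 neither. Sclerotome counts adjusted over the list alone were 1 and 11, and camera gave adjusted p = 2.2e-04 (adjusted p = 0.469 with an estimated correlation). For mesenchyme and matrix genes, 0 of 27 tested had a positive interaction, 7 a negative one and 20 neither. Matrix counts adjusted over the list alone were 0 and 10, and camera gave adjusted p = 3.2e-04 (adjusted p = 0.587 with an estimated correlation).

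Of the 14595 genes tested, 1298 had a positive and 1506 a negative interaction, and 1079 and 1051 of these reached 2-fold. With limma 74.1% of called genes were positive instead of 46.3% (median 0.24), with a pseudocount of 0.1 75.3% (0.28) and on rescaled FPKM 75.2% (0.26). The count fell to 1618 and 1597 without Ujumqin day 25 replicates 2 and 3 and to 1561, 1656 and 1578 without Hulunbuir day 25 replicates 1, 2 and 3. Between the ages, 82 genes were higher and 67 lower in Hulunbuir at both (97.3 and 108.2 for independent lists), and 151 were higher at day 16 and lower at day 25 and 190 the reverse (109.2 and 96.4). The breed contrasts of the ages correlated across genes with Pearson r = -0.10 and Spearman rho = -0.05.

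Each breed contrast was also set against the mean age contrast across genes, to ask whether breed differences ran along the axis of embryo age. Pearson r was 0.24 at day 16 (Spearman rho 0.29) and -0.21 at day 25 (rho -0.34). An exact two-sided permutation of the breed labels gave p = 0.3 at day 16, with 3 of 10 splits as large, and p = 0.2 at day 25, with 2 of 10, both 0.3 after Benjamini-Hochberg adjustment over the 2 ages. The smallest p these 10 splits allow is 0.1.

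Tail bud and axis genes were fixed for description because the experimental breed is named for its short tail. TBXT (chromosome 8, 87796143 to 87805552), the T-box gene of notochord and tail bud, was at 1.93 ± 1.25 FPKM in Ujumqin and 5.2 ± 3.28 in Hulunbuir at day 16 (log2 change 1.32 ± 0.65, adjusted p = 0.177). It fell with age in both breeds (-3.21 ± 0.74 and -4.42 ± 0.75). CDX2 (chromosome 10, 32304264 to 32309836), a caudal homeobox gene, also fell with age, with log2 changes of -6.05 ± 1.39 in Ujumqin and -5.89 ± 1.32 in Hulunbuir, with no call between breeds at 12.3 ± 8.02 and 17.4 ± 17.2 FPKM at day 16 (adjusted p = 0.8004). FGF8 (chromosome 22, 21678317 to 21686777), a growth factor gene of streak and tail bud, was at 0.546 ± 0.145 FPKM in Ujumqin and 1.67 ± 0.597 in Hulunbuir (log2 change 1.56 ± 0.43, adjusted p = 0.0309) at day 16. At day 25 it was at 2.08 ± 0.885 FPKM in Ujumqin and 1.78 ± 0.433 in Hulunbuir (log2 change -0.60 ± 0.42, adjusted p = 0.348), and its interaction was -2.16 ± 0.60 (adjusted p = 0.028). Its day 16 call was lost without Ujumqin replicate 2 or 3 or Hulunbuir replicate 1 (highest 0.0957), by limma (0.0620), after quantile normalization (0.176), in the 6 libraries alone (0.139) or with the block (0.0762) and by voom (0.336). Its interaction was lost in 6 of the 12 fits without 1 library (highest 0.0822) and in 5 other settings (0.0792 to 0.148). Those fits were the ones without Ujumqin day 16 replicate 2, Hulunbuir day 16 replicate 1, Ujumqin day 25 replicate 2 or 3 and Hulunbuir day 25 replicate 1 or 3. In Ujumqin FGF8 rose with age by 2.08 ± 0.43 (adjusted p = 0.0016).

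The T-box gene TBX6 (chromosome 24, 26206479 to 26210145) and the tail bud signal gene WNT3A (chromosome 5, 2734761 to 2784523) were not called between breeds. At day 16 TBX6 was at 1.56 ± 0.962 FPKM in Ujumqin and 3.32 ± 2.33 in Hulunbuir (log2 change 1.07 ± 0.66, adjusted p = 0.274). WNT3A was at 1.02 ± 0.69 FPKM in Ujumqin and 2.3 ± 2.26 in Hulunbuir (log2 change 1.05 ± 0.76, adjusted p = 0.357). CYP26A1 (chromosome 22, 14125228 to 14129084), which encodes a retinoic acid-degrading enzyme of the tail bud, was at 6.01 ± 5.61 FPKM in Ujumqin and 5.25 ± 4.36 in Hulunbuir at day 16 and at 2.08 ± 1.07 and 2.18 ± 0.395 at day 25. Without Ujumqin day 16 replicate 3 its age change in Ujumqin had an adjusted p of 0.0219. GDF11 (chromosome 3, 163428386 to 163435878), which acts in the trunk to tail transition, was at 6.14 ± 0.754 FPKM in Ujumqin and 9.58 ± 1.09 in Hulunbuir (log2 change 0.57 ± 0.21, adjusted p = 0.0765) at day 16. At day 25 it was at 5.41 ± 0.89 FPKM in Ujumqin and 10.5 ± 0.646 in Hulunbuir (log2 change 0.59 ± 0.21, adjusted p = 0.0744). Both differences passed the threshold in other settings, 5 at day 16 (0.0231 to 0.0488) and 7 at day 25 (0.00254 to 0.0354). HOXD13 (chromosome 2, 132912439 to 132915560), a terminal HOX gene, was at 2.53 ± 1.31 FPKM in Ujumqin and 4.65 ± 2.78 in Hulunbuir (log2 change 0.89 ± 0.56, adjusted p = 0.289) at day 16. Its age change in Hulunbuir had an adjusted p of 0.0247 without Hulunbuir day 16 replicate 3. MSGN1, a presomitic mesoderm gene on chromosome 3, 25804320 to 25805692, had 44, 35 and 41 counts in Ujumqin and 51, 59 and 0 in Hulunbuir at day 16 and 0 in the 6 day 25 libraries. HOXB13 (chromosome 11, 37337231 to 37338988) had 12, 0 and 8 counts in Hulunbuir at day 25 and 0 elsewhere. Neither was tested.

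PDGFD (chromosome 15, 3848546 to 4133998), a growth factor gene proposed for fat tail size in sheep, was at 7.31 ± 0.352 FPKM in Ujumqin and 4.67 ± 0.195 in Hulunbuir (log2 change -1.01 ± 0.31, adjusted p = 0.0439) at day 25. That call was lost without any of the 6 day 25 libraries (0.0990 to 0.139) and in 4 other settings (0.0770 to 0.275). In Ujumqin PDGFD rose with age from 2.62 ± 1.55 to 7.31 ± 0.352 FPKM (log2 change 1.64 ± 0.31, adjusted p = 8.6e-04). In Hulunbuir it went from 3.17 ± 1.13 to 4.67 ± 0.195 FPKM (log2 change 0.44 ± 0.30, adjusted p = 0.274). The interaction was -1.21 ± 0.43 (adjusted p = 0.0717). Without Ujumqin day 16 replicate 3 the adjusted p was 0.00253 for the interaction and 0.0311 for breed at day 16. In 4 other settings the interaction was called (0.0196 to 0.0461).

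**Figure D3:**
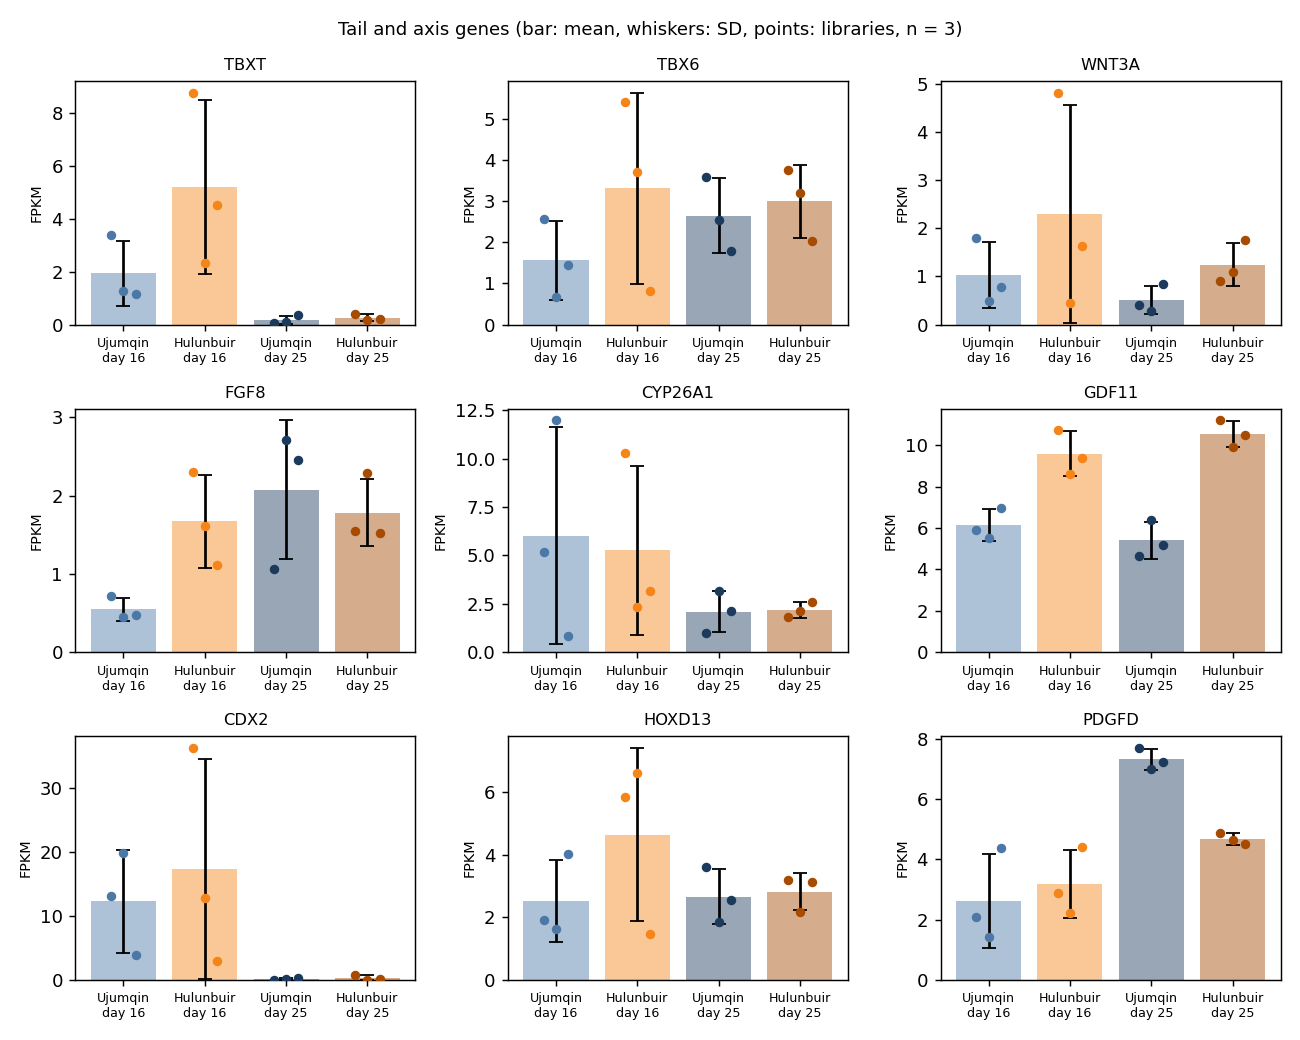
FPKM of 9 tail and axis genes in the 4 groups, with bars for the mean, whiskers for the SD and points for the 3 libraries of a group. Bars start at 0; TBXT lay at 1.93 ± 1.25 and 5.2 ± 3.28 FPKM at day 16 and at 0.171 ± 0.159 and 0.256 ± 0.135 at day 25, and PDGFD at 7.31 ± 0.352 and 4.67 ± 0.195 at day 25 in Ujumqin and Hulunbuir.

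The zeta globin, ribosomal protein, keratin, actin and serpin genes belong to families with close copies or pseudogenes, so their counts are uncertain if copies shared reads.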

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

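In this part, the tests of exchanged breed labels, of tissue share, of gene length, of depth and of extraembryonic tissue were chosen only after the result was seen. The results below are those where a test found that the breed effect differed between day 16 and day 25. It did for 2804 genes. Of 100 splits drawn from 200 the real one alone reached 2804, and another gave 2160. Splits mix breeds within each age and ignore the day 16 pairing, so they cannot exclude an equal breed effect at both ages. Of single genes, BLVRB (4.30), CREG1 (3.53), SLC22A4 (5.78) and FHL2 (2.72) had positive and SLC22A17 (-2.41) and ITGA7 (-3.15) negative log2 interactions. Median log2 interactions of called lists were 4.96 for erythroid, 3.59 for yolk sac, endoderm and liver, -0.97 for primitive streak and tail bud, -1.07 for anterior and middle HOX, -1.60 for somite and muscle, -1.15 for heart, -1.44 for sclerotome, -1.31 for mesenchyme, -0.87 for endothelium, -0.54 for glycolysis, -0.77 for ribosomal protein and -1.76 for mitochondrially encoded genes. With an estimated correlation 0 of these 12 lists were called (adjusted p = 0.304, 0.469, 0.590, 0.562, 0.587, 0.694, 0.469, 0.587, 0.590, 0.694, 0.587 and 0.570 in the same order). The primitive streak call was lost without Ujumqin day 16 replicate 2 (0.0751) or 3 (0.0761) or Hulunbuir day 16 replicate 1 (0.295), the heart call without Ujumqin day 16 replicate 2 (0.0851) or Hulunbuir day 16 replicate 3 (0.172), and the glycolysis call without Ujumqin day 16 replicate 2 (0.0726) or 3 (0.202) or Hulunbuir day 16 replicate 1 (0.146). Of the 100 splits, 61 gave at least 12 lists (highest other 18), so chance is not excluded for the number of lists.

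Erythroid and yolk sac or liver genes were lower in Hulunbuir at day 16 and higher at day 25. The tables argue against a few abundant genes taking the counts, since the erythroid median stayed at least 2.03 log2 units from that of all genes at both ages under median-of-ratios and quantile scaling. Breed labels exchanged at 1 age cannot be told apart from the labels as given: of 13928 genes outside the 29 lists, 195 separated the breeds as labelled with no overlap and 228 with the labels exchanged. A larger share of blood, yolk sac or liver tissue in some samples is a candidate source that stays open: 17 of 25 erythroid members were lower at day 16, and 0 of the 25 erythroid and 2 of the 32 yolk sac members stand on another list. HBZ reached 1618 ± 1444 and 87.1 ± 31.1 FPKM at day 16 and 2029 ± 269 and 15669 ± 1556 at day 25 in Ujumqin and Hulunbuir, AHSG 20028 ± 11389, 3802 ± 2909, 2708 ± 756 and 10249 ± 478, and a breed difference in the timing of these tissues is open and untested.

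Ribosomal protein transcripts were lower in Hulunbuir at day 25. With TMM, gene length alone is argued against. The median of -0.86 lay below 1000 random gene sets of the same lengths (-0.50 to 0.12, median -0.22). A part from length is open. Scaling between libraries stays open. Quantile normalization left a median of -0.14 relative to all genes, inside the 0.3 set in advance, and other scalings -0.76 to -0.86. A breed difference is open and untested.

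Day 16 libraries of a group lay farther apart than day 25 libraries. Depth is argued against, since the lowest day 16 total, 43.13 (in units of 1e+06 counts), lay above the highest day 25 total (39.64). Varying extraembryonic tissue could not be tested: the trophoblast list's spread lay at percentile 100 of random sets, but 24 of the 29 lists lay at or above percentile 95, and 6 of its 17 members stand on another list. Its most abundant member, KRT8, was at 2139 ± 815 and 2906 ± 1479 FPKM in Ujumqin and Hulunbuir at day 16. Embryos at different stages cannot be told apart from other causes, since 0 of the 6 day 16 libraries reached an absolute r of 0.3 with the age contrast, with r from -0.22 to 0.25, and no other biological explanation was tested.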

How the results depend on the processing

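In this part, limma on log2(FPKM + 1), DESeq2, voom with group weights and the list and overlap settings beyond estimated correlation and block were chosen only after the result was seen. The day 16 breed count of 2459 moved most. It was 3 with the 6 libraries alone, 293 with the replicate block added, 487 with voom, 3696 with DESeq2 and 1494 with a 2-fold criterion. Fits without 1 library gave 1167 to 3361 (lowest without Ujumqin replicate 2, highest without Ujumqin replicate 3). The fit giving 3 has its own spread and 6 fewer libraries, and these were not told apart: in simulated data with the spread of each age it recovered 13% of 4-fold changes, against 76% with 86 false of 193 calls in the shared fit. The fit giving 487 has weights of 0.42, 0.39, 1.62 and 3.75 for Ujumqin and Hulunbuir at day 16 and then day 25. The day 25 count of 2440 was 3667 with limma, 4284 on rescaled FPKM, 6716 with the 6 libraries alone, 6482 with the block added, 6665 with voom, 1039 with a 2-fold criterion and 898 to 2074 without 1 library. The age count in Hulunbuir (5913) was 3467 with a 2-fold criterion and 4129 to 5573 without 1 library, that in Ujumqin (9284) 8084 to 9072, the interaction (2804) 1561 to 3337 and the shared age response (4628) 3332 to 4874. In that simulation the shared fit recovered 6% of 2-fold changes at day 25 and the 6 libraries alone 60%. Day 25 genes not called can thus have changed. The cause of the limma, DESeq2 and left-out-library shifts was not tested. With an estimated correlation camera called 0, 0, 0, 2 and 0 lists at day 16, day 25, in Ujumqin, in Hulunbuir and for the interaction, against 18, 9, 11, 18 and 12 with the preset one, the 2 being interferon response and fat tail candidates. Without 1 library there were 11 to 20 lists at day 16 (fewest without Hulunbuir replicate 3), 8 to 9 at day 25, 11 to 14, 17 to 19 and 10 to 13. The mesenchyme list at day 16 turned from up to down without Hulunbuir replicate 2 (adjusted p = 0.00579), with adjusted p up to 0.957 without Ujumqin replicate 2, and the cause was not tested. Correlations of breed with age contrasts lay between 0.161 and 0.347 at day 16 and between -0.243 and -0.176 at day 25 without 1 library.

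With the replicate number as a block over 12 libraries the counts were 2309, 2364, 9223, 5856 and 2626, the overlap 4617 and the lists 18, 9, 11, 17 and 12. At day 25 same-numbered libraries correlated with r of 0.0545, 0.0589 and 0.0315, each best with its own number, a hint from the data alone, and across ages with r from -0.0904 to 0.102, so those numbers were not taken as pairs. Among printed results the block changed no other call than those given beside PDGFD and the posterior and anterior HOX and mitochondrial lists and in the 6-library fits. Of 30 checked genes called at day 16, 1 was called with the 6 libraries, 18 with the block added, 18 by voom and 26 to 30 elsewhere. At day 25 29 to 31 of 31 were, with 30 of 30 by DESeq2. For age 37 to 40 of 40 and 33 of 33 were, and for the interaction 6 to 7 of 7, with 0 reversed.

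A comparison of 3 with 3 libraries makes 10 splits, too few for a share under 0.05. The real gene counts and the highest of other splits were 2459 and 686 at day 16, 2440 and 0 at day 25, 9284 and 0 in Ujumqin and 5913 and 0 in Hulunbuir, and 1 split reached the real count in each. At day 16 the 3 other splits that part the replicate numbers gave 0 genes each. List counts were 18 and 17 (1 split as large), 9 and 10 (2), 11 and 17 (8) and 18 and 18 (2), so other splits call about as many lists. For the shared age response, 1 of 100 splits reached 4628 (highest other 0), but other splits called 0 genes in each breed, so this does not test whether the overlap exceeds chance.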

Other observations

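In this part, the tests of functional terms were chosen only after the result was seen. Functional terms were tested by the one-sided hypergeometric test with Benjamini-Hochberg adjustment over 2147 terms, against 12786 tested genes with a term. Genes higher at day 25 in both breeds held 12 of 18 genes of the proteasome core (2.56 by chance, adjusted p = 1.9e-04), 18 of 32 of respiratory complex I assembly (4.56, 1.8e-05) and 17 of 45 of RNA splicing (6.41, 0.0153). Genes lower at day 25 in both held 48 of 111 genes of the apical plasma membrane (21.03, 6.9e-06) and 26 of 53 of the basement membrane (10.04, 1.3e-04).

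Between breeds at day 25, genes higher in Hulunbuir held 7 of 10 heme biosynthesis genes (0.848 by chance, adjusted p = 0.00633). Genes lower in Hulunbuir held 21 of 51 genes of the spliceosome (4.53, 2.1e-07) and 10 of 32 of collagen trimers (2.84, 0.0274). The gene sets of this part rest on TMM scaling alone, without a test of gene length. RXFP2, a receptor gene linked to horns (chromosome 10, 29454677 to 29502617), was chosen after its values were seen. It was at 535 ± 212, 709 ± 175, 378 ± 22.4 and 586 ± 99.98 FPKM in Ujumqin and Hulunbuir at day 16, then day 25. It was not called in the 4 contrasts, and reads of other genes were not excluded.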
